A study of Sus scrofa with 4 samples.

How the data were processed

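RNA from the liver of 4 Chinese miniature pigs was measured on 4 Affymetrix porcine expression arrays, 1 array per pig. Such an array reads each transcript with a set of short probes, a probe set, and several probe sets can stand for the same gene. Biotin-labelled cRNA was made from 6 ug of total RNA per pig, per the labels' protocols. The labels put 2 pigs in the control group and 2 in the clenbuterol group, and name replicate 1 of each group as male and replicate 2 as female.

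The log2 expression values deposited by the authors come from GCRMA, per the file headers and the submitters' processing notes. As a method, GCRMA corrects the background with probe sequence, equalises the distributions of the arrays and summarises each probe set on the log2 scale. The medians of the deposited values were 6.67 and 6.66 in the control and 6.62 and 6.61 in the clenbuterol arrays. Its version and settings are not given in the sources used here. That table lists 15383 probe sets. Its columns show the group, through the deposited log2 group means, but no replicate number or sex. A second deposited table, the series value table, holds 1 intensity per probe set and array on a linear scale for 24123 probe sets, including 124 array control probe sets, and its columns carry the replicate number. How the authors made these intensity values is not given in the sources used here. Their mean after trimming 2% at each end was about 500.1 on every array, so they had been scaled. The authors' deposited table also gives a signed fold as a score, a limma p-value, a q-value from SAM and another column with a 0 or 1 flag for probe sets chosen by both tools, per the file headers. The deposited limma p-values lay within 0.0136 of Benjamini-Hochberg adjusted p-values recomputed over all 15383 probe sets, so they were read as adjusted.

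Gene symbols came from the deposited annotation, updated by gene ID through a pig gene table of the Sscrofa11.1 assembly, which was used for names only. Of the probe sets, 2192 had 1 symbol, 23 had several and 13168 had none, and 2051 were matched by gene ID. Many symbols came from merged transcript clusters: 94 probe sets were listed as tubulin alpha. A symbol was therefore used only where the array design's own description of the probe set named the same gene, which held for 1236 probe sets and 1027 genes. This rule was set after the annotation was read.

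Probe sets with a log2 GCRMA value of at least 4 on at least 2 of the 4 arrays were tested, which left 11931 probe sets, 984 of them named, for 831 genes. Clenbuterol was compared with control by lmFit and eBayes of limma 3.58.1 in R 4.3.3 on the GCRMA values, with group alone in the model and Benjamini-Hochberg adjustment at 0.05. Because GCRMA columns carry no sex, the comparison of males with females and the response within each sex used log2 of the intensities for the same probe sets, a departure from the plan, which had put both on the GCRMA values. With 1 pig per sex and group, the difference in response between sexes has no residual degrees of freedom and was described without a test. The number of arrays limits the precision of every value. Each SD is over 2 arrays.

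In all, 47 gene lists were fixed beforehand. Those with at least 3 measured genes, 34 lists, were tested with camera from limma at a preset correlation of 0.01 between genes and again with an estimated correlation, on the brightest tested probe set of each gene, with adjustment over the lists. Named genes followed a rule set before the data were examined, as were the design and most of the alternative settings. At most 1 probe set per gene was taken, past the adjusted threshold, with a difference of at least 0.585 (log2) and the same sign in the male and the female pair, and the 12 largest higher and 12 largest lower differences were named. For males against females the rule allowed 8 and 8, with free places open to genes at an unadjusted p under 0.01. Up to 4 members of each list with the smallest p were named as well. A few genes that met the rule are not reported here. No probe set was listed as XIST. The 1 probe set listed as UTY, a Y-linked gene, was at most 3.23 (log2) on every array and below the filter. Probe sets without a gene symbol were not searched for other Y-linked genes, so the sex labels were not checked.

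The fits were tested on simulated data with 200 changed probe sets among 11931. For clenbuterol against control, 22 of 50 probe sets changed by a log2 difference of 1 were recovered, 46 of 50 changed by 2, 49 of 50 changed by 3 and 0 of 50 changed by 0.585. For males against females the counts were 0, 19, 38 and 0 of 50. In 50 simulated draws for the list test on 831 genes, without correlation between genes, a shift of 0.5 in the interferon list was called 50 times, with another list called in 4 of those draws, and no list was called without a shift. No gene outside that list changed in these draws, whereas 253 of the 831 genes had a called probe set in the data. The rate therefore does not carry over to the data. With 2843 probe sets called in the data, the recovery counts for clenbuterol against control do not carry over either. Alternatives covered the filter, the variance prior, added normalization, the other deposited table, the threshold, leaving out each array, a replicate block and how genes were named and summarised.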

Results

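Clenbuterol, a β2-adrenergic agonist, was fed to 2 Chinese miniature pigs, and 2 control pigs received the same diet without it. Feeding started at 8 weeks of age, at an average weight of 18 kg, at 25 mg/kg given 2 times daily for 4 weeks and 50 mg/kg for the next 4 weeks. Liver RNA was taken at 4 months of age and hybridised to 1 array per pig. Each group held 1 male (replicate 1) and 1 female (replicate 2). The design text says that groups were made of full sibs of the same sex. Read with the sex labels, this fits sib pairs of 1 sex split between treatments, but the wording leaves it open whether sibs shared a treatment instead. The median of the tested probe sets ranged from 8.95 to 8.98 (log2 intensity) over the 4 arrays.

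The first comparison asks how 8 weeks of clenbuterol in the diet changed expression in the liver. In the treated pigs, transcripts of the chemokines CXCL2, CCL19 and CCL2 and of the lipogenic enzymes SCD and FASN were among those higher, and those of the plasma proteins MBL2, APOA4 and APCS were among those lower. CXCL2, a chemokine that attracts neutrophils, had a GCRMA value of 3.85 ± 0.16 (log2, SD, n = 2) in controls and 8.89 ± 0.14 in treated pigs. MBL2, the mannose-binding lectin that starts the lectin pathway of complement, was 12.98 ± 0.15 in controls and 8.99 ± 0.20 in treated pigs, 15.9-fold lower. CYP7A1, the rate-limiting enzyme of bile acid synthesis, was 10.65 ± 0.06 in controls and 12.85 ± 0.01 in treated pigs, 4.59-fold higher. By limma, 2843 of 11931 probe sets passed an adjusted p of 0.05, of which 1365 were higher and 1478 lower with clenbuterol, and 683 of them differed by at least 2-fold. The split depended on the scaling. In the series values it was 690 higher and 636 lower, and 1895 and 300 after scaling to the hybridisation spikes added to each array.

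Among the named genes with the largest rises, 3 encode chemokines: besides CXCL2, CCL19 rose 4.16-fold and CCL2, which attracts monocytes, rose 3.70-fold. NPG4, an antibacterial peptide of the cathelicidin family, rose from a control value of 2.14 ± 0.07 (log2), near the floor of the array, to 4.79 ± 0.40. RGS1, a regulator of G-protein signalling, rose 6.19-fold, TCN1 (haptocorrin, a vitamin B12 binder) 5.30-fold and FADS2, a fatty acid desaturase, from 3.23 ± 0.19 to 5.17 ± 0.25. DIO1, the deiodinase that turns thyroxine into triiodothyronine, rose 3.60-fold, from 6.59 ± 0.22 to 8.43 ± 0.01. YWHAZ rose from 3.62 ± 0.65 to 6.01 ± 0.68, and LOC733638, listed as a zinc finger protein, rose 4.57-fold. The control values of CXCL2, NPG4, FADS2 and YWHAZ lay below the filter of 4, so the sizes of these rises depend on how dim signals were summarised. Adjusted p for these genes lay between 0.00114 and 0.0293, and each was higher in both the male and the female pair, as the naming rule required.

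A probe set for CBR1, carbonyl reductase, had the largest fall of the named ones in the GCRMA values. It was at 8.68 ± 0.07 in controls and 4.01 ± 0.04 in treated pigs, close to the filter of 4. In the series values the mean difference was larger for MBL2, at −3.54 (log2) against −3.06. A second probe set for CBR1 went the other way, from 4.28 ± 0.16, also close to the filter, to 7.37 ± 0.22, and by 2.22 (log2) in the male and 1.84 in the female pair of the series values, so no single direction holds for this gene. DIRAS3, a small GTPase, was at −4.00 ± 0.31 (log2 difference, SE), with a treated value of 3.48 ± 0.44 that lay below the filter, APOA4, an apolipoprotein of lipid transport, was 6.61-fold lower and APCS, serum amyloid P, 3.47-fold lower. The catalytic phosphatase subunit PPP1CA was 3.34-fold lower, the calcium channel subunit CACNA2D1 3.26-fold lower and the potassium channel KCNB2 3.24-fold lower. VNN1, a pantetheinase, was 2.79-fold lower, RGS5 2.58-fold lower and the calpain subunit CAPNS1 2.46-fold lower. A probe set listed as Thy-1 cell surface antigen was 2.50-fold lower, though the array design describes it as a co-transcribed neighbour. Adjusted p for these 12 genes lay between 0.00101 and 0.0428. Sizes depended on the deposited table: in the series values the mean difference was −3.06 (log2) for the first CBR1 probe set against −4.67, −2.50 for DIRAS3 against −4.00, and 1.09 for CCL19 against 2.06, and it was also over 1.5 times smaller for NPG4, TCN1 and FADS2.

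**Figure D1:**
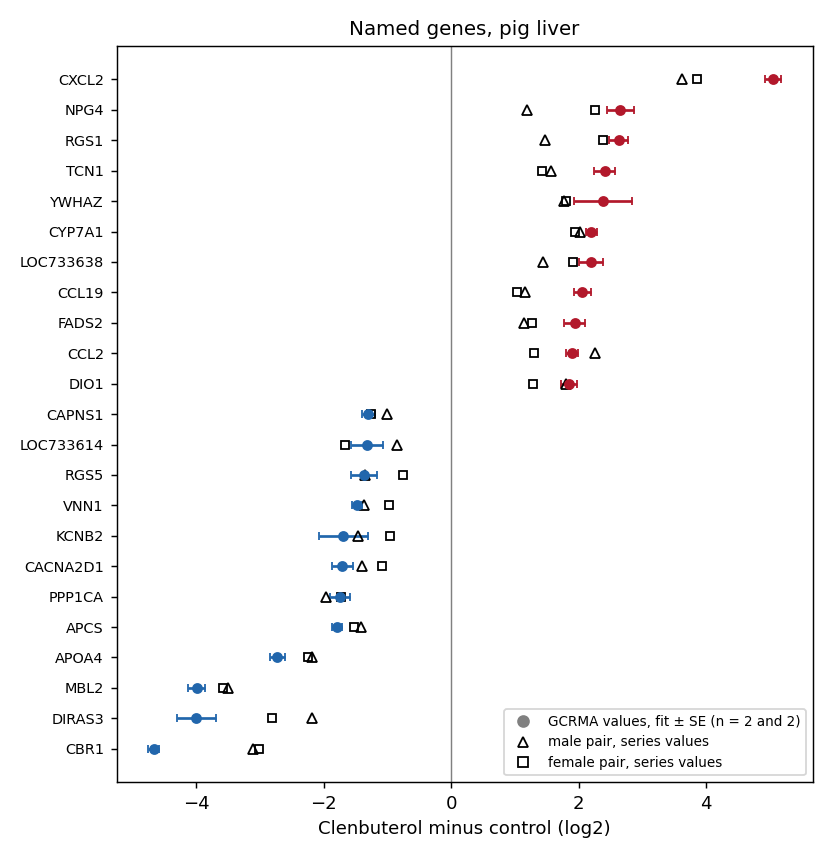
Log2 difference between clenbuterol and control pigs for the named genes. Filled points are limma differences of GCRMA values with their standard errors (n = 2 pigs per group), and open triangles and squares are the differences in intensity within the male and the female pair. Both pairs lie on the same side of 0 as the fitted value for every gene shown, because the rule for naming genes required it.

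Of all 831 named genes tested, 253 had at least 1 called probe set in either direction, which is the share to set beside the list counts that follow. It is not quite like them: the list counts use only the brightest probe set of each gene, whereas this share takes any, and so can run higher. In the interferon response list, 8 of 14 measured genes rose and none fell past the threshold, 9 when adjusted over the list alone. OAS1, a sensor of double-stranded RNA, rose by 0.91 ± 0.08 (log2, SE), USP18 by 1.01 ± 0.11 and the immunoproteasome subunit PSMB8 by 0.75 ± 0.08. ISG20 rose from 3.53 ± 0.27 (SD) in controls, below the filter of 4, to 4.71 ± 0.04, and by 1.30 in the male and 0.44 in the female pair of the series values. For antigen presentation, 4 of 8 genes rose and none fell past the threshold, 6 adjusted over the list alone: the MHC class I gene SLA-3 by 1.08 ± 0.09 (SE), PSMB9 by 1.02 ± 0.17, CD74, the invariant chain of MHC class II, by 1.25 ± 0.20, and PSMB8. PSMB8 and PSMB9 belong to both lists. In the acute phase list, 8 of 25 genes rose and 1 fell, CEBPB at −0.42 ± 0.09, a gene named after its value was seen, with 11 past the threshold adjusted over the list alone. HAMP, which encodes the iron hormone hepcidin, rose by 1.73 ± 0.15 and CRP by 0.86 ± 0.09. For complement and coagulation, 5 of 21 genes rose and MBL2 fell, 8 in all adjusted over the list alone. C7 rose by 1.40 ± 0.14, the coagulation factor F9 by 0.87 ± 0.09 and C2 by 0.47 ± 0.09.

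Lipid and sterol genes moved in both directions. In fatty acid and triglyceride synthesis, 5 of 8 genes rose and 1 fell, 7 adjusted over the list alone. The desaturase SCD rose by 1.66 ± 0.09, fatty acid synthase FASN by 1.51 ± 0.13 and the acyltransferase GPAM by 0.95 ± 0.08, whereas malic enzyme, ME1, was lower, at −1.05 ± 0.08. In cholesterol synthesis, INSIG1, a brake on sterol synthesis, rose (adjusted p = 0.00602 by limma), and SREBF2 and CYP51 were lower, at −0.36 ± 0.08 and −0.38 ± 0.09, although in the series values SREBF2 was at 0.01 in the male pair and −0.76 in the female pair, so that 3 of 5 genes passed, 4 adjusted over the list alone. In fatty acid oxidation, 2 of 13 genes rose and 1 fell, 3 adjusted over the list alone: CPT1A was at 0.42 ± 0.08, ETFB at 0.37 ± 0.08 and the acyl-CoA synthetase ACSL1 at −0.90 ± 0.08. Of 11 genes of lipoprotein assembly only APOA4 passed, over all probe sets and over the list alone. Of 4 genes of lipolysis and lipid droplets, 0 passed by limma, with unadjusted p under 0.05 for CES1 alone, which was at −0.29 ± 0.08. Only 2 genes of bile acid synthesis and transport were measured, too few for a list test, and both CYP7A1 and the exporter ABCC2 (0.96 ± 0.08) rose.

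Of the genes of the clenbuterol target pathway, β-adrenergic signalling, 2 of 6 rose and none fell past the threshold, 2 adjusted over the list alone. This is near the share over all named genes, 253 of 831, and camera gave this list an unadjusted p of 0.856. The 2 genes were RGS2, at 1.14 ± 0.09, and PRKACB, a catalytic subunit of protein kinase A, at 0.46 ± 0.10. Among 3 measured genes of cAMP-responsive transcription, the coactivator PPARGC1A was at 0.82 ± 0.10 and JUN at 1.09 ± 0.20, both past the threshold also over the list alone, and IGFBP1 was at −0.02 ± 0.08. JUN and MYC, at 0.47 ± 0.11, were also the 2 measured genes of the list of early response and handling genes, and both passed. In gluconeogenesis, GOT1 (0.91 ± 0.10) and MDH1 (0.34 ± 0.08) rose, and PCK2 (−0.56 ± 0.09) and PC (−0.60 ± 0.11) fell, among 9 genes, the same number when adjusted over the list alone. The glucose transporter SLC2A2 rose by 1.02 ± 0.09 and was the only one of 5 glycolysis genes to pass. In the growth hormone and IGF axis, IGFALS was at 0.71 ± 0.15 and IGFBP3 at −0.64 ± 0.14, and 8 of 10 genes did not pass. Adjusted over the list alone, 2 genes of this axis and 1 of glycolysis passed.

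In the cytochrome P450 list, 5 of 21 genes rose and none fell past the threshold, 8 adjusted over the list alone, among them CYP2C42 (1.12 ± 0.08), CYP2D25 (1.16 ± 0.09), CYP1A1 (1.02 ± 0.08) and CYP2C49 (0.47 ± 0.08). Of 7 genes of phase II conjugation, SULT1E1 (0.54 ± 0.09) and SULT1A3 (0.44 ± 0.08) rose. Among 16 antioxidant genes, GPX3 (−0.95 ± 0.13), TXNRD1 (−0.73 ± 0.09) and SOD2 (−0.47 ± 0.09) fell and PRDX6 (0.46 ± 0.08) rose, 4 adjusted over the list alone. In amino acid catabolism, 4 of 10 genes rose and 1 fell, FTCD, also named after its value was seen, at −0.97 ± 0.22, with KMO at 0.55 ± 0.08, AMT at 0.85 ± 0.13 and BHMT at 0.46 ± 0.09. Of 4 urea cycle genes, only GLUL, glutamine synthetase, passed, at −0.87 ± 0.09. None of 31 cytosolic ribosomal protein genes, 8 genes of oxidative phosphorylation or 6 heat shock genes passed by limma, over all probe sets or over the list alone. At an unadjusted p under 0.05 there were 3 ribosomal protein genes, among them RPL13A and RPS15, 2 of oxidative phosphorylation (ATP5O and SDHB) and 0 heat shock genes. Smaller sets among the lists were cell cycle, with 3 of 8 genes higher and 1 lower (GADD45A, −0.95 ± 0.08), apoptosis, with 2 of 6 higher, the proteasome, with 2 of 8 higher, and the tricarboxylic acid cycle, with 2 of 13 higher and 1 lower (SUCLG2, −0.36 ± 0.08). Among 8 thyroid and glucocorticoid genes only DIO1 passed, and among 8 sex-biased liver genes only SULT1E1. Adjusted over the list alone, the numbers that passed were 5 for amino acid catabolism, 4 for cell cycle, 4 for the proteasome, 3 for apoptosis, 3 for the tricarboxylic acid cycle, 2 for phase II conjugation and 1 each for the urea cycle, thyroid and sex-biased lists. Glycogen metabolism (PGM1, UGP2) and endoplasmic reticulum stress (HSPA5, HSP90B1) had too few measured genes for a list test, and none of those 4 genes passed.

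Cell type markers were set beside these groups. None of 8 hepatocyte markers passed by limma, with 0 at an unadjusted p under 0.05, and their median difference was −0.02 (log2). Of the stellate cell and fibroblast markers, 4 of 10 rose, among them COL1A1 (1.42 ± 0.11), TIMP1 (1.01 ± 0.14) and DCN (0.71 ± 0.08), and RGS5 fell. In the series values TIMP1 was at −0.23 in the male pair and 0.97 in the female pair. Among 9 Kupffer cell and macrophage markers CD14 (0.70 ± 0.08) and AIF1 (0.37 ± 0.08) rose. Among 6 T and NK cell markers CD2 rose, by 0.89 ± 0.11. Of 7 endothelial markers CLDN5 (0.94 ± 0.19) and PECAM1 (0.39 ± 0.09) rose and VWF (−0.96 ± 0.09) fell, and of 4 cholangiocyte markers CLDN4 (−0.52 ± 0.08) and GGT1 (−0.74 ± 0.12) fell. None of these 5 kept its call in the series values, where CLDN5 was at 0.35, PECAM1 at 0.17, VWF at −0.69, CLDN4 at −0.29 and GGT1 at −0.27. Adjusted over the list alone, the numbers that passed were 0 for hepatocytes, 5 for stellate cells, 5 for Kupffer cells, 1 for T and NK cells, 3 for endothelium and 3 for cholangiocytes. The neutrophil, B cell and erythroid lists had no measured gene under the symbol rule, although probe sets that the array design describes as hemoglobin were tested. The single measured marker each of muscle (TPM2), adipocytes (CFD) and exocrine pancreas (AMY2) did not pass. A measure of RNA length moved with the treatment as well, in 7 of 10 pairs of 3′ and 5′ control probe sets for pig transcripts: for 1 of the GAPDH pairs the gap was 1.68 and 1.81 (log2) in the control pigs and 1.03 and 1.28 in the treated pigs. Several of the 7 pairs were for GAPDH. All differences are relative to the deposited scaling, and scaling the intensities to the spikes added to each array would move the median of all tested probe sets to 0.24 (log2).

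**Figure D2:**
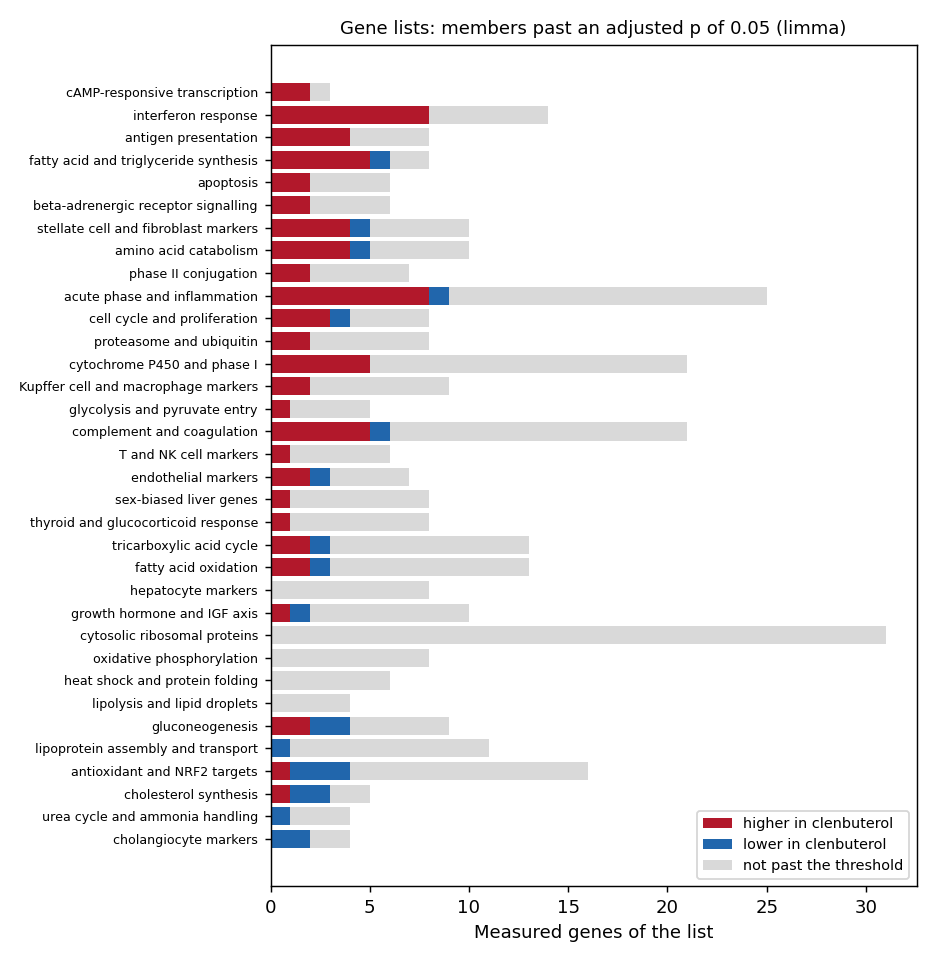
Measured genes of each list that passed an adjusted p of 0.05 in the limma comparison of clenbuterol with control, higher (red) or lower (blue), and those that did not pass (grey). The interferon list has 8 of 14 genes higher, and the ribosomal protein list has none of 31 past the threshold.

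As a competitive test, camera placed 0 of 34 lists past an adjusted p of 0.05. The smallest values were 0.204 for the interferon response and 0.237 for antioxidant genes, and with an estimated correlation the smallest adjusted p was 0.821. The direction camera gave was down for gluconeogenesis, ribosomal proteins, cell cycle, the growth hormone axis and endothelial markers, whose median and mean differences were above 0, and for fatty acid oxidation and the urea cycle, whose median alone was above 0. The unadjusted p at the preset correlation was under 0.05 for 4 lists, which also included antigen presentation (0.0213) and fatty acid synthesis (0.0362). The number of single probe sets past the threshold depended on every array, since leaving out any 1 of the 4 left between 579 and 1213 calls, and on the table, with 1326 calls in the series values. Among the genes with the largest changes, YWHAZ, KCNB2, RGS5 and the Thy-1 probe set lost the call when an array was left out, YWHAZ, KCNB2 and the Thy-1 probe set also without the filter, and the Thy-1 probe set also in the series values with a replicate block. In the series values without a block, 32 of all 93 named probe sets lost it.

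The authors' deposited table flags 691 probe sets, 336 higher and 355 lower, all with a fold of at least 2.00 in the authors' deposited table. Of these, 669 were among the tested probe sets, and 649 of them passed here. The flag rests in part on limma fits of the same GCRMA values, so this overlap is not an independent check.

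The second comparison asks whether the male and the female pig responded alike. Within the male pair and within the female pair, 328 probe sets differed by at least 2-fold in the same direction, 172 higher and 156 lower with clenbuterol, and 1 differed by that much in opposite directions, against 516 and 73 without the filter. Across the 11931 probe sets, which are not independent replicates, the differences of the 2 pairs had a Pearson correlation of 0.717 (0.438 without the filter) and a Spearman correlation of 0.660. CXCL2 was higher by 3.62 (log2 intensity) in the male pair and 3.85 in the female pair, and MBL2 was at −3.50 and −3.57. CCL2 was higher by 2.26 in the male pair and by 1.30 in the female pair, and RGS1 by 1.47 and 2.38. With 1 pig per sex and group these differences have no replicate check.

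**Figure D3:**
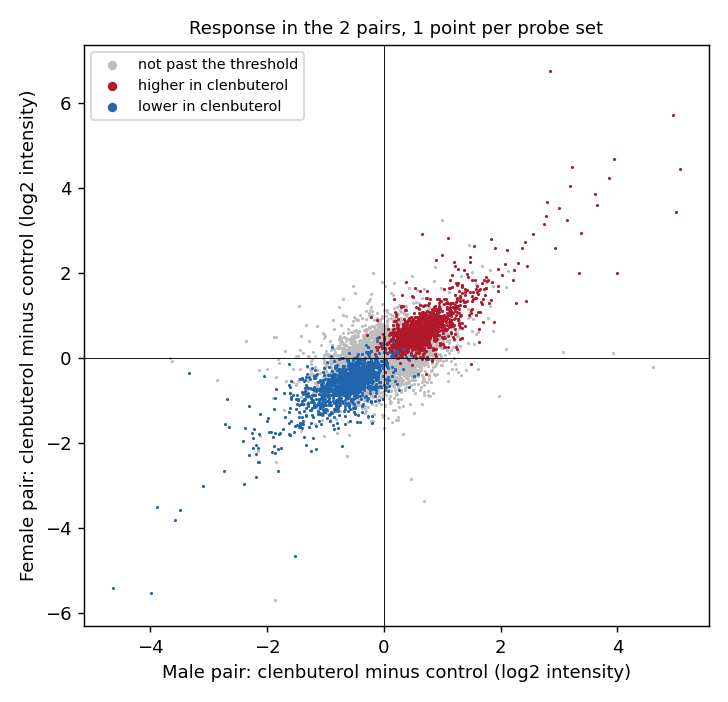
Log2 difference in intensity between the clenbuterol and the control pig, in the male pair (horizontal) and the female pair (vertical), 1 point per tested probe set, coloured by its call in the GCRMA comparison. The Pearson correlation across probe sets is 0.717.

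Males and females were compared over both treatments, with sex, replicate number and possibly litter inseparable. A single probe set of 11931 passed in limma, at 8.57 ± 0.09 (log2 intensity, SD, n = 2) in males and 14.16 ± 0.06 in females, 48.2-fold lower in males with an adjusted p of 0.0185. Its gene is uncertain: the deposited annotation lists it as APOA1, while the array design describes it as weakly similar to a splicing factor. The next probe sets by p did not pass but were also lower in males, by 25.4-, 7.17- and 19.0-fold. Control probe sets for ribosomal RNA differed with the replicate number as well, as given below. At an unadjusted p under 0.05 there were 161 probe sets. No named gene met the rule. Among the lists, hepatocyte markers were lower in males by camera (adjusted p = 0.00023, median difference −0.16), and the adjusted p was 0.987 with an estimated correlation. Without the control female or the clenbuterol male, 0 lists passed, and without either female 0 probe sets passed, against 6 without the clenbuterol male. None of the 8 markers passed singly, with APOB at −0.79 ± 0.32 (SE), SERPINA1 at −0.23 ± 0.16 and CYP2E1 at −0.18 ± 0.16. Treatment was not in this model, so differences between the treatments counted as spread. With treatment as a covariate the count was also 1, and the adjusted p for hepatocyte markers was 0.0155.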

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

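All 9 tests of explanations in this part were chosen after the results they bear on, or closely related values, had been seen. For the test on probe sets of the same cluster, the bootstrap interval was also added to the rule after its median ratio was known. The test of RNA length first used 3 transcripts alone, and the test of MHC alleles outside the heavy chains first counted 3 genes, before genes of the MHC region were left out.

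A single unnamed probe set moved in opposite directions by at least 2-fold in the 2 pairs: its intensity was lower with clenbuterol in the male pair (−1.45, log2) and higher in the female pair (1.23). The difference was not tested, as each value rests on 1 pig.

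Among control probe sets outside the comparisons, the 5′ probe sets of GAPDH and actin were brighter in the treated pigs, by 0.507 and 0.498 (log2 intensity), while their 3′ probe sets were at −0.080 and −0.002. Hybridisation spikes, added in a fixed amount, were dimmer with clenbuterol for all 27 probe sets (median −0.394), as were all 36 poly-A spike probe sets (median −0.510).

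Large differences between the groups could have technical sources, and if alleles shared within a treatment group changed probe binding, other probe sets of the same transcript cluster would not follow. For 27 of the 103 called probe sets changed at least 4-fold such a partner was tested, and the median ratio of the partner's difference was 0.706 (95% bootstrap interval 0.345 to 0.955), with 16 ratios of at least 0.5 and 7 under 0.25. The median lies above the bound of 0.5 first set for a change in the transcript, which alone would have counted against allele effects, and the interval added later lies above 0.25, the bound set for allele effects, but reaches below 0.5, so with most of the 103 lacking a partner the 2 cannot be told apart for the set as a whole. For the 152 called probe sets changed 2 to 4-fold that had a partner, the median ratio was 0.454, between the 2 bounds. Of these ratios, 72 were at least 0.5 and 44 under 0.25. A difference in RNA length is also open: of 10 pairs of 3′ and 5′ control probe sets for pig transcripts, 7 had a larger gap on both control arrays than on both treated arrays and 3 did not. Gaps of the 3 varied more between arrays of 1 group, such as −0.51 and −2.48 (log2) on the control arrays for the CTLA4 receptor. The 10 pairs are not separate transcripts: several of the 7 were for GAPDH, and actin pairs went both ways. Labelling that reached less far to the 5′ end on the control arrays is argued against by the poly-A spikes. There 1 of 12 pairs, several for each spike transcript, had a larger gap on both control arrays. Clenbuterol itself remains the explanation the design names, untested against these.

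Higher immune and antigen presentation genes could come from a changed mix of cells. More residual blood is argued against by a median difference of −0.341 (log2) over the 5 tested probe sets that the array design describes as hemoglobin, of which 3 were lower past the threshold and 0 higher. If a lower share of hepatocytes raised all other cell types alike, the cholangiocyte, stellate cell and endothelial lists would rise. Of their 21 members 6 were higher and 4 lower past the threshold. Of those 4, only RGS5 kept its call in the series values. These lists hold no immune cells, so they cannot decide whether more immune cells lowered the hepatocyte share. None of 8 hepatocyte markers passed by limma, with a median difference of −0.02 (log2). Some of them, SERPINA1, CYP2E1 and TF, were very bright, with means by sex of 14.6 to 15.1 (log2 intensity). A small fall in the hepatocyte share could go unseen in such probe sets, so these markers do not decide it. MHC alleles that differ between the treatment groups are consistent with the class I heavy chain probe sets, whose differences ran from −1.81 to 4.46 with an SD of 1.49, though 10 of the 16 were higher and 1 lower past the threshold (median 0.704) and 3 probe sets carry most of the spread, and for PSMB8 and PSMB9, which lie in the MHC region, such alleles cannot be told apart from a rise, as only 1 called gene of the list, CD74, is encoded elsewhere. A change in the immune cells themselves, through the treatment or otherwise, stays open.

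The probe set called between sexes goes with the replicate number, at −5.62 (log2, male minus female) in controls and −5.57 in treated pigs. More ribosomal RNA of every kind on the replicate 2 arrays is argued against by an 18S control probe set that was brighter on both replicate 1 arrays, by at least 1.81, although the other 4 ribosomal RNA probe sets were on average brighter on the replicate 2 arrays. Another 18S probe set was at 6.97 and 6.73 (log2 intensity) on the replicate 1 arrays and 11.84 and 11.98 on the replicate 2 arrays. A 28S probe set differed by −2.95 (replicate 1 minus replicate 2). The test therefore does not bear on more ribosomal RNA of particular kinds on the replicate 2 arrays. Sex, litter and any shared handling of the replicate 2 arrays cannot be told apart, because they coincide in the labels.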

How the results depend on the processing

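The fits of the series values with a replicate block or scaled to the spikes, and the use of every deposited gene symbol, were chosen after seeing the data. The 2843 calls between clenbuterol and control stayed within 1.5 times under the filters, the variance priors, added normalization and a threshold of 0.10 (range 2350 to 4206). They fell to 1326 in the series values, 672 at an unadjusted p under 0.01 with at least 2-fold, and between 579 and 1213 when an array was left out, where the lone array is assumed to vary like the other group. The cause was not tested beyond the fewer arrays. No replicate block was fitted to the GCRMA values, whose columns carry no replicate numbers and were not matched to the replicates by their values. In the series values it left 1054 calls, and same-numbered pigs deviated together with a correlation of 0.177 across probe sets, which with 2 pairs does not settle whether the numbers pair the pigs. Scaling the series values to the hybridisation spikes gave 2195 calls but moved the median of all probe sets to 0.243 (log2) and the split to 1895 higher and 300 lower, against 690 and 636 without it. Under it GGT1 turned to 0.00196. Where tested, the 93 named probe sets otherwise kept their sign, and 32 lost the call in the series values, 41 with the block, 34 to 55 when an array was left out (most without a clenbuterol array, 55 and 48) and 59 under at least 1 alternative. No gene list was called for the treatment under the alternatives run. Between sexes, the count was 0 without the filter, 10 at an unadjusted p under 0.01 with at least 2-fold, and between 0 and 6 when an array was left out. The call for hepatocyte markers was lost, leaving 0 lists, with an estimated correlation and with quantile normalization, and leaving out an array gave between 0 and 1 list. The other deposited table was not used for sex, as its columns carry none and were not matched to the labelled arrays by their values. Both pairs moved the same way by at least 2-fold for 516 probe sets without the filter, with 73 in opposite directions (against 1) and a Pearson correlation of 0.438 (against 0.717), and for 1201 and 43 with the filter at 1.5-fold and 4-fold, with 28 and 0 in opposite directions. Without the filter on dim probe sets 2350 were called, and with a stricter filter 2987.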

Other observations

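The groups of probe sets described here were chosen after their values were seen, from words in the array design's descriptions, and were compared with all other tested probe sets by Fisher's exact test, two-sided, with adjustment over all 16 words tried. The words for immunoglobulins were widened after a first count. Probe sets are not independent replicates, so these p-values describe the array. Of 5 kinds of immunoglobulin chain, transcripts of antibody-producing cells, gamma was higher with clenbuterol by 3.87 ± 0.24 (log2, SE), kappa by 2.87 ± 0.21, lambda by 1.89 ± 0.15 and mu by 1.49 ± 0.14, whereas the alpha constant region did not pass and was at −0.13 ± 0.11. The first 4 were higher in the male and in the female pair. A probe set moderately similar to CD79A (immunoglobulin-associated alpha) did not pass and was at −0.09 ± 0.09. Of 18 probe sets with the word chemokine in their description, 8 were higher and 1 was lower (adjusted p = 0.00233 for the share of higher calls), but 4 of the 18, 1 of them among the higher, are chemokine-like factors rather than chemokines or receptors. The 8 higher included the receptor CXCR4, at 1.82 ± 0.14, and a probe set weakly similar to CXCL13, a B cell attractant, which went from 2.88 ± 0.01 (SD) in controls, below the filter of 4, to 5.57 ± 0.15. CXCL12, the ligand of CXCR4, was at −0.14 ± 0.13.

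Of 48 probe sets described as proteasome subunits or partners, 15 were higher and 0 lower (adjusted p = 0.00156), a larger set than the 8 named genes of the proteasome list. Among 29 described as cytochrome P450, 9 were higher and 2 lower (adjusted p = 0.0124). Among 70 solute carriers, 16 were higher and 8 lower (adjusted p = 0.0183). Collagens, with 8 of 33 higher and 3 lower, and glutathione-related probe sets, with 6 of 24 higher and 1 lower, both had an adjusted p of 0.0978. Heat shock probe sets, with 5 of 30 higher, had an adjusted p of 0.555. Histocompatibility probe sets, which overlap the antigen presentation list, had 19 of 31 higher and 1 lower (adjusted p = 6.68e-10), and probe sets with immunoglobulin words in their description 6 of 13 higher and 1 lower (adjusted p = 0.00746). Only 5 of those 13 are immunoglobulin chains, of which 4 were higher and 0 lower. The other words gave adjusted p-values of 0.123 for ribosomal protein, 0.317 for interferon, 0.636 for mitochondrial, 0.749 for hemoglobin or globin, 0.837 for actin or myosin and 1 for metallothionein and keratin.

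Of 24 genes with at least 2 called probe sets, 21 had all of them in 1 direction. The exceptions were CBR1, MTHFD1 and SHMT1. For MTHFD1 the probe sets were at −0.34 ± 0.08 and 0.84 ± 0.11, and for SHMT1 at 0.51 ± 0.10 and −0.40 ± 0.08. The last 2 genes encode enzymes of folate metabolism.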
